A study of Macaca mulatta with 12 samples.

How the data were processed

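RNA was measured in 12 liver biopsy libraries from 6 male rhesus macaques, each biopsied before and at the end of a 90-day ethanol induction. Per the labels, 500 ng of total RNA with a RIN above 8.5 went into a NEXTFLEX Combo-Seq preparation, which makes mRNA and miRNA libraries from 1 sample and pools them, and reads of 76 bases were taken on an Illumina NovaSeq. The 4 groups were light drinkers (LD) and very heavy drinkers (VHD) at baseline and post-induction, with 3 libraries each. Animals were matched across time points by the numbers in the sample titles.

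The deposited raw tables hold expected counts, per Ensembl transcript for mRNA and per mature miRNA for miRNA. The processing notes of the authors name Partek, Bowtie, BWA and the build Mmul_8.0.1, but the tool versions, the annotation release and which aligner made which table are not given in the sources used here. Values of the transcript table were whole numbers in 40.1% of cells, those of the miRNA table in all but 4 of 903 miRNAs. No transcript had a total under 10 over the 12 libraries, and the largest values came rounded to 3 significant digits. The deposited normalized tables hold signal values, which equalled the raw count times 1 constant per library, and they were used only in an alternative.

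The 40611 transcripts were summed into 23993 genes by the gene identifier in the transcript table, and the sums were rounded. Summing per gene symbol had been planned. It was replaced because 48 symbols stood on more than 1 identifier, which were kept apart, and because 8522 identifiers had no symbol in the reference used here. Identifiers without a symbol took 16.2 to 17.6% of the counts of a library. Positions are given as in the transcript table. Whether its start counts from 0 or 1 could not be settled, so a start may differ by 1 base.

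Genes and miRNAs with low counts were removed with filterByExpr by group, which left 18373 genes (13611 with a symbol) and 427 miRNAs. Changes were tested in R 4.3.3 with edgeR 4.0.16: TMM factors, a quasi-likelihood fit of the 4 group means over all 12 libraries with robust dispersion, the quasi-likelihood F test, and Benjamini-Hochberg adjustment within each comparison and assay with a threshold of 0.05. The 6 comparisons were VHD against LD at baseline and post-induction, post-induction against baseline within LD and within VHD, the difference of these responses, and their mean. The standard error of a log2 fold change was its size divided by the square root of F. Libraries of 1 animal were treated as independent, because no paired model was stated, and a term for the animal was an alternative for the responses, their difference and their mean. Between LD and VHD, which share no animal, the term was the number in the titles. Abundances are given as CPM, the depth-scaled count of edgeR, with library totals scaled by the TMM factors.

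Without sight of the values, 45 gene lists (871 names, 689 found in the table and 671 tested) and 8 miRNA lists were written down for metabolic pathways, stress and immune responses and cell types. The 44 gene lists and 7 miRNA lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. The table names miR-122 as miR-122a, and this match was added after the first list results had been seen.

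Named genes followed a rule fixed at the same time. Of the genes past the threshold with a symbol and an average log2 CPM of at least 1 (3 for miRNAs), it took the 10 with the largest rise and the 10 with the largest fall. Where fewer than 3 passed in a direction, it took the 5 with the smallest unadjusted p as values. It added up to 4 members of each list past the threshold or with a changed member, and a panel of CYP2E1, ADH4, ALDH2, FGF21, CYP7A1, miR-122, miR-21, miR-34a and miR-223. ALDH2 of the panel matched no identifier. Genes outside the rule are marked where they appear. Some results that the rule takes are not reported here.

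Settings varied as laid down before the data were examined were DESeq2 1.42.0 with its size factors, RLE and upper-quartile factors, no filter and a filter of 1 CPM in 3 libraries, a term for the animal or number, limma voom with the animal as a random effect, fits to the compared groups alone, limma-trend on log2 of the deposited normalized values plus 1 or 0.1, transcripts in place of genes, and leaving out each library. Chosen after seeing the data were fits without the 2 libraries VHD baseline 3 and VHD post-induction 2, without animal VHD3, with a term that parts 5 libraries from the other 7, with 2 surrogate variables (sva 3.50.0), without small RNA genes, without miR-122, and with miR-122a left unmatched. Genes on in some libraries and off in others were those with at least 8 CPM in the first and at least an 8-fold gap between the groups, on CPM without the TMM factors.

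Library totals were 5970033 to 25060718 transcript counts and 127740 to 613359 miRNA counts (median 295821). The common biological coefficient of variation was 0.457 for genes and 0.627 for miRNAs. The methods were tested on simulated data with 200 changed genes or 60 changed miRNAs at the depths and spread of these libraries. The changed ones were drawn from those with an average log2 CPM of at least 1. Counts were drawn independently for each gene or miRNA, without the structure that the real libraries share. The recovery and false calls given here therefore need not hold for the real data. In the VHD response, edgeR recovered 0, 32.8 and 84.8% of genes changed 2, 4 and 8-fold, with 2 false calls among 80. In the mean response it recovered 7.46, 89.6 and 98.5%, with 7 false calls among 137. For miRNAs the shares were 0, 15 and 65% in the VHD response and 5, 70 and 95% in the mean response. DESeq2 made 28 false calls in the VHD response and 33 in the mean response. DNA methylation and protein data were not analysed here. No reference genome was at hand, so GC content and untranslated regions were not examined.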

Results

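The liver was sampled by biopsy in 6 male rhesus macaques of about 4.6 years, before and after an ethanol induction of 90 days. The dose was 0.5, then 1, then 1.5 g ethanol per kg per day, for 30 days each, and was alike for all animals. During the following 12 months of free access 3 animals became light drinkers (LD, 1.5 g per kg per day) and 3 very heavy drinkers (VHD, 4 g per kg per day). The classes therefore name later drinking, and the baseline comparison is between livers sampled before the induction. Each class had 3 libraries at baseline and 3 post-induction, from the same animals.

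Transcript counts of LD baseline 1, 2 and 3 were 5970033, 16983241 and 15658621, and those of LD post-induction were 21530865, 14062577 and 10526716. VHD baseline had 11092756, 13304252 and 25060718, and VHD post-induction had 7180516, 18058690 and 20103894. Mature miRNA counts in the same order were 127740, 281671 and 309970 for LD baseline, 420249, 611883 and 359662 for LD post-induction, 242259, 394409 and 235288 for VHD baseline, and 157174, 214582 and 613359 for VHD post-induction. Between 20704 and 23348 genes were detected per library. Spearman correlations were 0.871 to 0.958 within groups and 0.854 to 0.966 between groups, so the groups were not tighter than the whole set. Component 1 of the mRNA values (31.4% of the variance) parted LD post-induction 2 and 3, VHD baseline 2 and VHD post-induction 1 and 3 from the other 7 samples, a division that holds 4 post-induction libraries and 1 baseline library and so partly goes with time. VHD post-induction 1 lay in between on this component, at 7.224. It was closer to VHD baseline 3 (-5.606) than to VHD baseline 2 (45.2). Component 2 (20.6%) set VHD baseline 3 (-92.65) and VHD post-induction 2 (-82.31), which also had the lowest miRNA counts per 1000 transcript counts (9.39 and 11.9), apart from the rest.

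**Figure D1:**
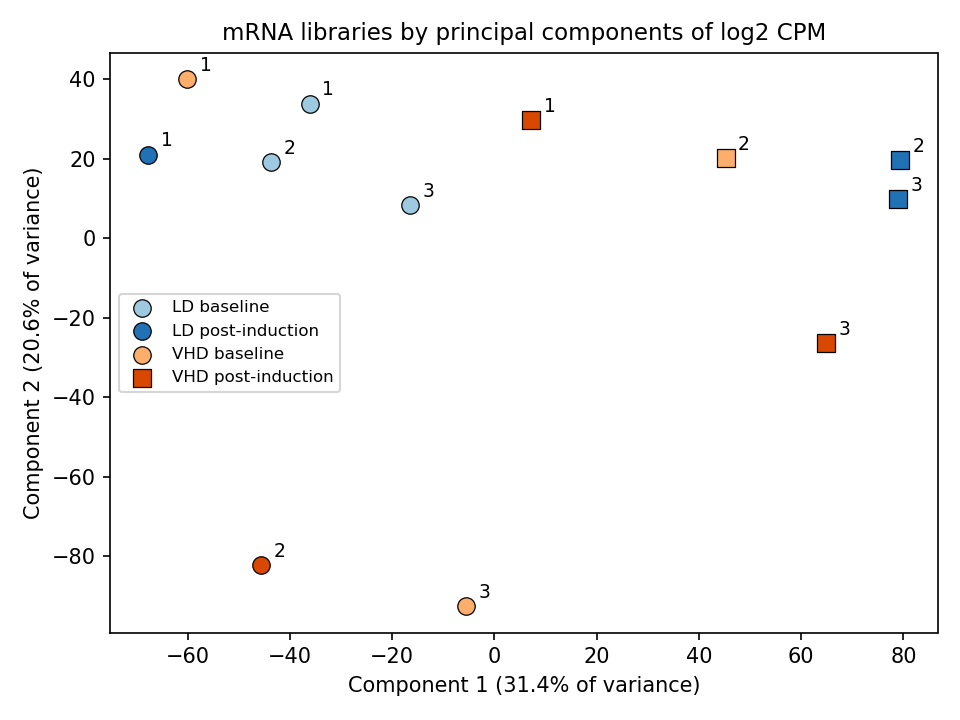
Principal components of log2 CPM of the mRNA libraries: each point is 1 library, the colour gives its group, the number its animal within the class, and squares mark the 5 samples in which SLC15A2 stood at 44.6 to 169 CPM, against 7.40 CPM or less in the other 7 (circles). Component 1 (31.4% of variance) holds the 5 squares on its right side, with VHD post-induction 1 near the middle (7.224). Component 2 (20.6%) sets VHD baseline 3 and VHD post-induction 2 at -92.65 and -82.31.

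The response of the liver to the induction was first taken as the mean of the LD and VHD responses (6 animals). Of 18373 genes, 46 fell and 3 rose, and every one named here moved the same way in 6 of 6 animals. The largest falls were those of RGCC, a regulator of the cell cycle that responds to complement, by 30.1-fold, and JUNB, a subunit of the AP-1 transcription factor, by 13.5-fold (log2 fold change -4.91 ± 0.73 and -3.75 ± 0.61 SE, adjusted p = 0.0246 and 0.0268). MYC, a transcription factor of growth (-2.91 ± 0.44, adjusted p = 0.0246), ZFP36, which speeds the decay of inflammatory mRNAs (-2.86 ± 0.40, adjusted p = 0.0246), and KLF6, an injury-induced transcription factor (-2.40 ± 0.27, adjusted p = 0.0117), also fell. KLF6 went from 179 ± 61.6 to 41.2 ± 19.4 CPM in LD and from 193 ± 40.8 to 30.2 ± 2.27 CPM in VHD (SD, n = 3 each). Falls were also seen in IL1RN, the interleukin 1 receptor antagonist (-2.37 ± 0.43, adjusted p = 0.0403), PLIN2, a coat protein of lipid droplets (-2.26 ± 0.35, adjusted p = 0.0246), TNFRSF12A, the receptor of TWEAK (-2.24 ± 0.36, adjusted p = 0.0268), and IHH, a hedgehog ligand (-2.19 ± 0.37, adjusted p = 0.0268). The 3 that rose were SCG3, a secretogranin (3.19 ± 0.56, adjusted p = 0.0336), PAEP, the secreted lipocalin glycodelin (2.92 ± 0.48, adjusted p = 0.0268), and PDE4B, a phosphodiesterase that breaks down cyclic AMP (1.20 ± 0.21, adjusted p = 0.0363). PDE4B went from 5.44 ± 0.954 to 14.0 ± 1.92 CPM in LD and from 6.13 ± 0.503 to 12.7 ± 2.84 CPM in VHD.

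In Mmul_8.0.1 coordinates of the transcript table, KLF6 (ENSMMUG00000010696) lies on chromosome 9 from 3679835 to 3688584 on the minus strand, and RGCC (ENSMMUG00000011593) on chromosome 17 from 20701186 to 20712756 on the plus strand. The edgeR test gave 1454 genes at an unadjusted p under 0.05, where 919 would be met by chance, and DESeq2 called 269 (73 higher, 196 lower). With a term for the animal 4 of the 49 passed and no others, KLF6 among them, and on transcripts in place of genes 0 passed. The count was 12 without LD baseline 2, 1 without LD baseline 3, 0 without LD post-induction 2, 4 without LD post-induction 3, 1 without VHD baseline 1, 31 without VHD baseline 2, 0 without VHD post-induction 1 and 2 without VHD post-induction 3, while all 49 kept their direction. The call of KLF6 held in 23 of 26 alternatives, that of ZFP36 in 19, that of PLIN2 in 18 and that of RGCC in 17, and those of PDE4B and IHH in 12 and of IL1RN in 11.

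**Figure D2:**
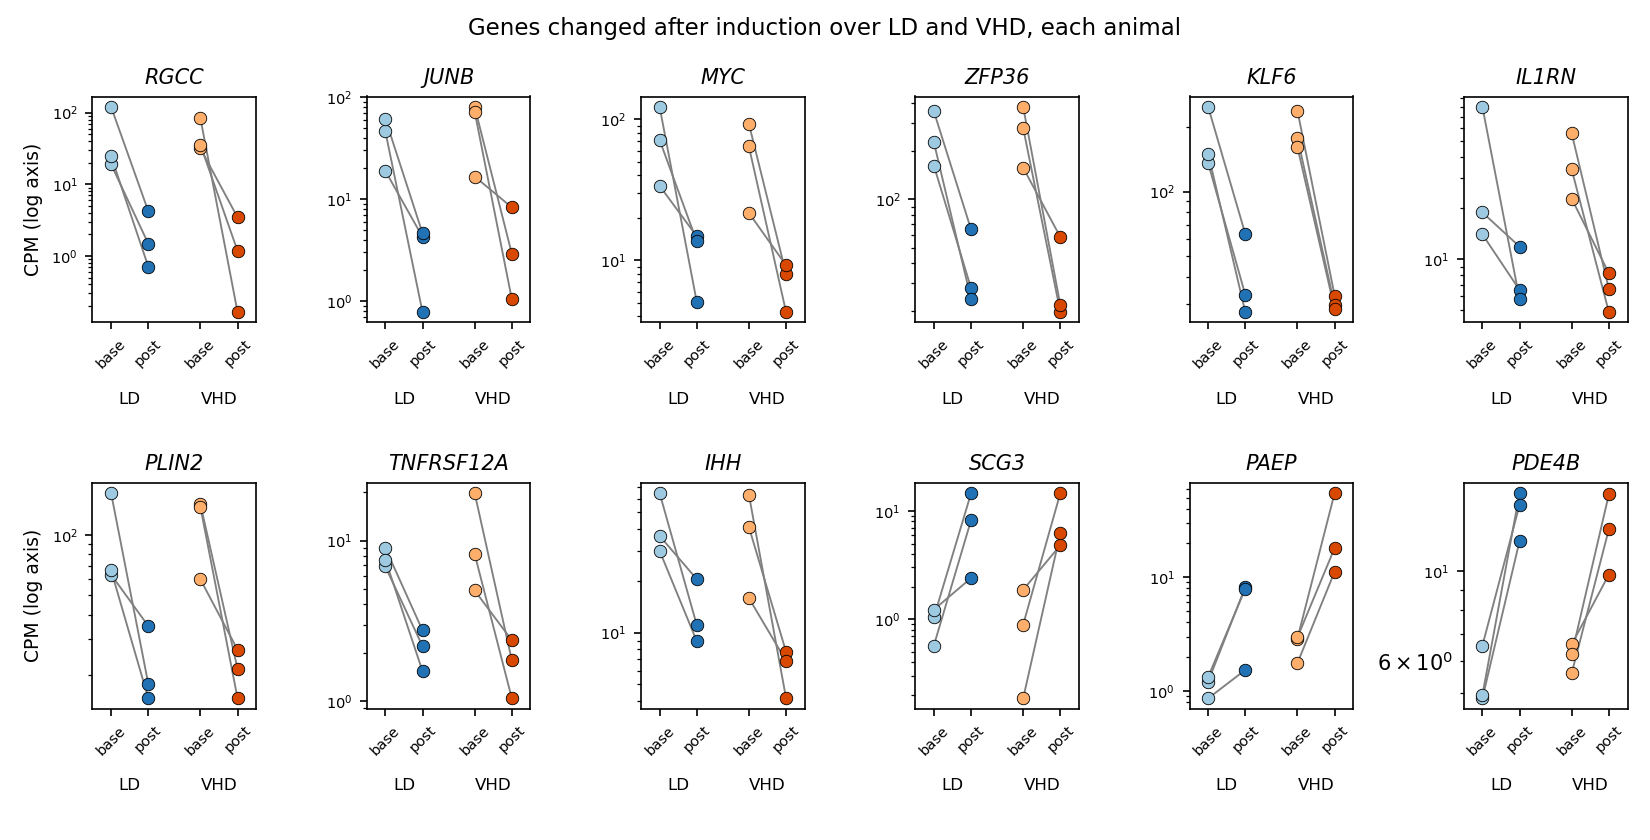
CPM (log axis) of 12 genes that changed after the induction, at baseline and post-induction in LD and VHD: each point is 1 library and each line joins the libraries of 1 animal. Of these genes 9 were lower and 3 (SCG3, PAEP, PDE4B) higher post-induction in 6 of 6 animals, and KLF6 in VHD went from a mean of 193 to 30.2 CPM.

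By gene list, the immediate early genes, which cells switch on shortly after a stimulus, fell as a group and in 6 of 6 animals (median log2 change -1.24, 14 of 17 negative, adjusted p = 2.67e-13; adjusted p = 0.331 with an estimated correlation). Of the 17, 5 fell over all genes tested, KLF6, ZFP36, MYC and JUNB among them, and 10 did so adjusted over the list alone. The acute phase proteins, which the liver secretes in inflammation, also fell as a group in 6 of 6 animals (median -0.58, 18 of 20 negative, adjusted p = 2.64e-08; adjusted p = 0.645 with an estimated correlation). None of their 20 genes passed over all genes and 3 did adjusted over the list alone. Their leading values were those of the iron hormone HAMP (-2.02 ± 0.40, adjusted p = 0.065) and of CRP (-2.27 ± 0.49, adjusted p = 0.0919). HAMP went from 2615 ± 1543 to 616 ± 322 CPM in LD and from 2747 ± 338 to 713 ± 426 CPM in VHD (SD, n = 3). Both lists held without any single library.

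Smaller falls were found for the oxidative stress response (median -0.24, 12 of 19 negative, adjusted p = 0.0142), the autophagy and lysosome list (-0.11, 13 of 20 negative, adjusted p = 0.0142) and the inflammatory cytokines and NF-kappaB targets (-0.42, 9 of 15 negative, adjusted p = 0.0303). These 3 adjusted p became 0.376, 0.725 and 0.554 with an estimated correlation. In the first SRXN1, which repairs oxidised peroxiredoxins, fell (-1.37 ± 0.23, adjusted p = 0.0268), and 3 did adjusted over the list alone. In the second SQSTM1, an autophagy receptor, fell (-1.37 ± 0.24, adjusted p = 0.0357), and 1 did adjusted over the list alone. In the last IL1RN, which dampens inflammation, fell, and 3 did adjusted over the list alone. For the 26 names of this inflammatory list 15 identifiers were tested. IL1B, CXCL8, CXCL2, CXCL3, CCL3, CCL4, CCL5 and BIRC3 matched none, so many cytokines it is named for were not measured in any comparison. The oxidative stress list missed the threshold without LD post-induction 3 (adjusted p = 0.0599), the autophagy list without LD post-induction 2 (0.076) or VHD baseline 1 (0.0683), and the inflammatory list without LD post-induction 1 (0.0546), LD post-induction 2 (0.0601), VHD baseline 1 (0.0997) or VHD post-induction 2 (0.0844). Each list fell in 5 of 6 animals, the first 2 rising in LD animal 1 and the last in LD animal 3. In this order they also missed it with a term for the 5 and 7 samples (0.41, 0.484 and 0.0685) and with surrogate variables (0.232, 0.317 and 0.0683).

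Genes of lipid synthesis stood higher as 2 groups, each with adjusted p = 0.725 with an estimated correlation. The fatty acid and triglyceride synthesis list had a median of 0.46 (15 of 21 positive, adjusted p = 0.0333), with values of 1.10 ± 0.26 for the acetyl-CoA carboxylase ACACB (adjusted p = 0.133) and 1.29 ± 0.55 for the fatty acid synthase FASN (0.57). The cholesterol synthesis and uptake list had a median of 0.42 (13 of 16 positive, adjusted p = 0.0333), with 1.12 ± 0.29 for lanosterol synthase LSS (0.179) and 1.05 ± 0.36 for mevalonate kinase MVK (0.391). None of these genes passed over all genes, and in each list 1 rose adjusted over the list alone. The fatty acid list missed the threshold without LD baseline 1 (adjusted p = 0.0652), LD baseline 3 (0.124), LD post-induction 1 (0.216), VHD baseline 2 (0.268) or VHD post-induction 3 (0.0784). The cholesterol list did so without LD baseline 3 (0.0529), LD post-induction 1 (0.379), VHD baseline 1 (0.0683), VHD baseline 2 (0.0985) or VHD post-induction 3 (0.206). It also did so without animal VHD3 (0.0846). Cholesterol medians by animal were 1.11, -0.10 and -0.30 in LD and 0.51, 0.87 and 0.42 in VHD, so 2 of 3 LD animals went the other way, and the fatty acid list did in LD animal 2 (-0.06).

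Lists near the threshold were coagulation and complement (median -0.14, 20 of 27 negative, adjusted p = 0.034), p53 targets and apoptosis (-0.11, 10 of 11 negative, adjusted p = 0.0447) and, as markers of another cell type, the erythrocyte list (0.55, 7 of 7 positive and higher in 6 of 6 animals, adjusted p = 0.0495). The adjusted p were 0.876, 0.527 and 0.725 with an estimated correlation. No gene of these lists passed over all genes, and 1 of the p53 list fell adjusted over the list alone. Their leading values were -0.52 ± 0.23 for C4BPB, -1.03 ± 0.25 for the death receptor TNFRSF10B and 0.97 ± 0.43 for the globin chaperone AHSP. With a term for the animal the adjusted p of the p53 list was 0.0542. The coagulation list missed the threshold without LD baseline 1 or 2, LD post-induction 2 or 3, VHD baseline 1 or VHD post-induction 2 or 3 (adjusted p 0.0579 to 0.642), and the p53 list without LD baseline 3, LD post-induction 1 or 3, VHD baseline 1 or 2 or VHD post-induction 1 or 2 (0.064 to 0.15). The erythrocyte list did so without LD baseline 1 or 2, LD post-induction 2 or 3, VHD baseline 1 or 2 or VHD post-induction 2 or 3 (0.0531 to 0.321). With a term for the 5 and 7 samples coagulation (0.815) and the erythrocyte list (0.171) missed it, as they did with surrogate variables (0.854, with the direction turned, and 0.293). Without VHD baseline 3 and VHD post-induction 2 the p53 list (0.0877) and the erythrocyte list (0.165) did. Coagulation rose in LD animal 1 and VHD animal 3, and the p53 list in LD animal 2. The erythrocyte median was only 0.0237 in LD animal 1, and of its names HBA1, HBA2, HBB, HBD and HBM matched no identifier.

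Single genes fell in lists that did not pass. They were MAT2A, which makes S-adenosylmethionine (-1.53 ± 0.28, adjusted p = 0.0397; methionine, folate and glutathione list, 0.146), XBP1, a transcription factor of the unfolded protein response (-1.87 ± 0.33, adjusted p = 0.0357; endoplasmic reticulum stress list, 0.321), and SGK1, a kinase induced by glucocorticoids (-2.08 ± 0.34, adjusted p = 0.0268; glucocorticoid list, 0.255). PLIN2 belonged to the list of fatty acid oxidation and PPAR alpha targets (0.665). The genes of ethanol and acetaldehyde metabolism did not pass as a group (13 genes, adjusted p = 0.879): CYP2E1, the ethanol-oxidising cytochrome, had a value of -0.42 ± 0.27 (adjusted p = 0.764) and the alcohol dehydrogenase ADH4 one of -0.03 ± 0.31 (0.993). The hepatokine FGF21 was lower in 6 of 6 animals (-2.27 ± 0.52) and failed the adjustment (0.125). CYP7A1, the rate-limiting enzyme of bile acid synthesis, had a value of -0.78 ± 0.62 (0.811). The lists of heat shock proteins (adjusted p = 0.858), interferon-stimulated genes (0.879), macrophages (0.879), T and NK cells (0.879) and neutrophils (0.879) did not pass in the mean response either.

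**Figure D3:**
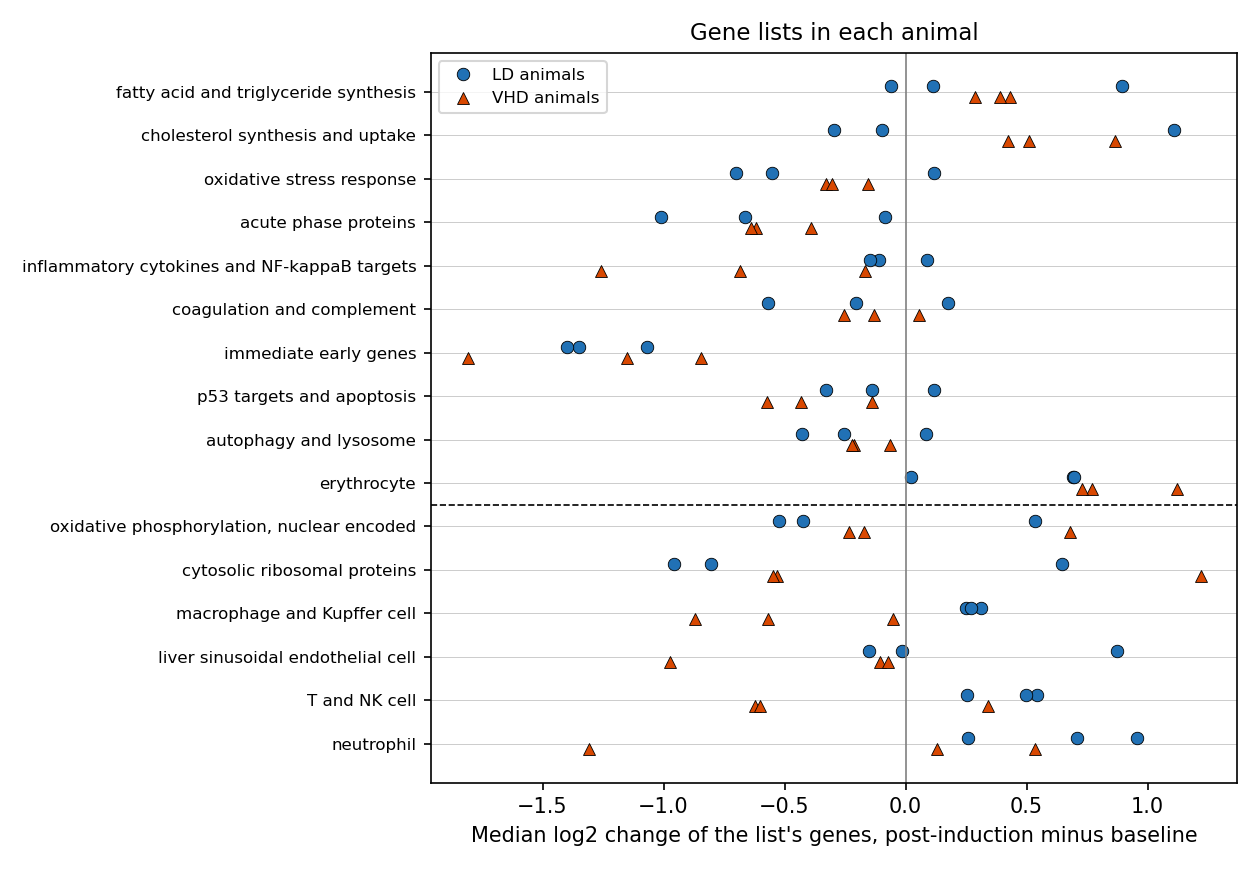
Median log2 change, post-induction minus baseline, of the genes of each list in each animal (circles, 3 LD animals; triangles, 3 VHD animals). Above the dashed line are the 10 lists past the threshold in the mean response, where immediate early genes and acute phase proteins lie below 0 in all 6 animals; below it are 6 further lists past the threshold in the difference between VHD and LD, where the macrophage list lies above 0 in 3 LD and below 0 in 3 VHD animals.

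Within LD animals the same question was asked of 3 baseline and 3 post-induction libraries. No gene passed, and the smallest unadjusted p among named genes belonged to genes lower in 3 of 3 animals: KLF6 (-2.12 ± 0.38), NIFK, a nucleolar protein (-1.58 ± 0.29), the RNA helicase DDX5 (-1.55 ± 0.29) and the receptor kinase EPHA2 (-1.95 ± 0.37), each with adjusted p = 0.482. DDX5 went from 383 ± 25.3 to 131 ± 17.6 CPM (SD, n = 3). Higher values were those of PDE4B (1.36 ± 0.30, adjusted p = 0.524) and SCG3 (3.17 ± 0.79, adjusted p = 0.601). The immediate early genes fell as a group (median -1.43, 13 of 17 negative, adjusted p = 9.38e-09; adjusted p = 0.446 with an estimated correlation), with FOS at -2.27 ± 0.49 and MYC at -2.77 ± 0.62, and 8 fell adjusted over the list alone. The acute phase proteins fell as well (median -0.57, 18 of 20 negative, adjusted p = 1.02e-05; adjusted p = 0.707 with an estimated correlation), with HAMP at -2.09 ± 0.57, CRP at -1.90 ± 0.69 and SERPINA3 at -1.48 ± 0.60, and 0 did adjusted over the list alone. Both held without any single library.

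Lower as groups in LD were also the cytosolic ribosomal proteins (median -0.15, 36 of 39 negative, adjusted p = 0.0014), the oxidative stress response (-0.25, 13 of 19 negative, adjusted p = 0.0094), coagulation and complement (-0.18, 22 of 27 negative, adjusted p = 0.0356) and autophagy and lysosome (-0.18, 15 of 20 negative, adjusted p = 0.0356). In the same order the adjusted p were 0.81, 0.446, 0.81 and 0.756 with an estimated correlation. Their first members had values of -0.55 ± 0.48 for RPL18, -1.40 ± 0.32 for SRXN1, -0.49 ± 0.33 for C4BPB and -1.28 ± 0.34 for SQSTM1. Adjusted over the list alone, 2 genes of the oxidative stress list and 1 of the autophagy list fell. In LD animal 1 all 4 lists rose (medians 0.65, 0.12, 0.17 and 0.09), and in LD animals 2 and 3 they fell. The ribosomal list missed the threshold without LD post-induction 2 (adjusted p = 0.103) or 3 (0.528), and with a term for the 5 and 7 samples its direction turned (5.72e-06); LD post-induction 2 and 3 are among the 5 and no LD baseline library is. The oxidative stress list missed it without LD post-induction 3 (0.103). Coagulation missed it without LD baseline 1 (0.0583), LD baseline 2 (0.0648), LD post-induction 2 (0.432) or LD post-induction 3 (0.0816), and autophagy without the same 4 libraries (0.0583, 0.0648, 0.3 and 0.11). The term for the 5 and 7 samples also ended the calls of oxidative stress (0.313), coagulation (0.752) and autophagy (0.575). So did surrogate variables (0.176, 0.655 and 0.585), with which the directions of coagulation and of the ribosomal list (0.000134) turned. For single genes edgeR called 0 in LD (1047 at an unadjusted p under 0.05, 919 by chance), limma voom and both limma-trend fits 0, and DESeq2 53 (4 higher, 49 lower).

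Within VHD animals KLF6 again had the smallest p, with a value of -2.68 ± 0.39 that failed the adjustment (0.182, lower in 3 of 3 animals). ZFP36 (-3.03 ± 0.57), TMEM201, a protein of the inner nuclear membrane (-1.68 ± 0.30), IRAK2, a kinase of interleukin 1 signalling (-2.05 ± 0.37), and the phosphate transporter SLC20A1 (-1.98 ± 0.36) each had adjusted p = 0.287. PAEP went from 2.54 ± 0.675 to 28.0 ± 23.5 CPM (3.45 ± 0.67, adjusted p = 0.287), and the secreted glycoprotein CHI3L1 from 437 ± 125 to 1652 ± 412 CPM (1.92 ± 0.47, adjusted p = 0.545; SD, n = 3). As groups the immediate early genes (median -1.23, 15 of 17 negative, adjusted p = 3.13e-15), the acute phase proteins (-0.60, 18 of 20 negative, 7.94e-07) and the inflammatory cytokines and NF-kappaB targets (-0.63, 11 of 15 negative, 2.56e-05) fell, in 3 of 3 animals. With an estimated correlation their adjusted p were 0.122, 0.562 and 0.122. Adjusted over the list alone 9, 3 and 4 of their genes fell, and 0 over all genes. Values were -3.78 ± 0.86 for JUNB, -2.64 ± 0.71 for CRP, -2.12 ± 0.58 for LBP, -2.51 ± 0.62 for IL1RN and -1.79 ± 0.46 for RELB. The 3 lists held without any single library. As said above, the inflammatory list was tested without IL1B, CXCL8 and several other cytokines.

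Cholesterol synthesis and uptake (median 0.64, 13 of 16 positive, adjusted p = 0.00101), fatty acid and triglyceride synthesis (0.45, 15 of 21 positive, adjusted p = 0.00392) and the erythrocyte markers (0.64, 7 of 7 positive, adjusted p = 0.0389) rose as groups in VHD, and the autophagy and lysosome list fell (-0.14, 12 of 20 negative, adjusted p = 0.0416). In this order the adjusted p were 0.562, 0.562, 0.595 and 0.663 with an estimated correlation. Values were 1.67 ± 0.51 for MVK, 1.13 ± 0.40 for LSS, 1.15 ± 0.36 for ACACB, 1.05 ± 0.39 for DGAT1, which makes triglycerides, 1.10 ± 0.58 for EPB42 and -1.47 ± 0.34 for SQSTM1. Adjusted over the list alone 1 gene of the autophagy list fell and 0 of the other lists passed. Cholesterol missed the threshold without VHD post-induction 3 (adjusted p = 0.185) and fatty acid synthesis without VHD baseline 2 (0.406) or VHD post-induction 3 (0.1). The erythrocyte list missed it without VHD baseline 1 (0.4), VHD post-induction 2 (0.476) or 3 (0.1), and autophagy without VHD baseline 1 (0.371), VHD baseline 3 (0.0676), VHD post-induction 2 (0.159) or 3 (0.165). The erythrocyte and autophagy lists missed it too with a term for the 5 and 7 samples (0.0911 and 0.466), with surrogate variables (0.112 and 0.17) and without VHD baseline 3 and VHD post-induction 2 (0.171 and 0.118). Without animal VHD3 cholesterol (0.0698) and autophagy (0.172) did. For single genes edgeR called 0 (632 at an unadjusted p under 0.05, fewer than the 919 by chance), limma voom and both limma-trend fits 0, and DESeq2 64 (4 higher, 60 lower). Without VHD post-induction 2 edgeR called 1.

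Whether the classes responded differently was tested as the difference of the responses, VHD minus LD. No single gene passed; the smallest unadjusted p were those of CD83, a marker of mature dendritic cells (-2.06 ± 0.61), and of the migration receptor GPR183 (3.67 ± 1.29), each with adjusted p = 1. CYP7A1 had a value of -3.17 ± 1.26 (adjusted p = 1), from 12.4 ± 3.27 to 21.5 ± 18.4 CPM in LD and from 26.0 ± 23.2 to 5.08 ± 3.405 CPM in VHD. Markers of several immune cell types and of endothelial cells moved lower in VHD relative to LD: T and NK cells (median -0.86, 9 of 9 negative, adjusted p = 0.000491), macrophages and Kupffer cells (-0.70, 10 of 10, 0.00307), neutrophils (-0.70, 10 of 11, 0.0162) and liver sinusoidal endothelial cells (-0.46, 9 of 11, 0.0288), with the inflammatory cytokines and NF-kappaB targets (-0.75, 14 of 15, 0.00291). With an estimated correlation none of these held: the adjusted p was 0.419 for T and NK cells, 0.641 for macrophages, 0.641 for neutrophils, 0.823 for sinusoidal endothelium and 0.419 for the inflammatory list. Values were -2.50 ± 0.99 for the granzyme GZMA, -1.13 ± 0.49 for the receptor CSF1R, -2.03 ± 0.79 for S100A8, -1.48 ± 0.64 for CLEC1B and -1.65 ± 0.83 for ICAM1. The cytosolic ribosomal proteins (0.25, 34 of 39 positive, 0.000156) and oxidative phosphorylation (0.20, 21 of 27 positive, 0.0288) moved higher (adjusted p = 0.823 for both with an estimated correlation), with RPS25 at 0.78 ± 0.76 and COX7A2 at 0.74 ± 0.80. The B and plasma cell list did not pass, and passed as higher only with a term for the animal. Its medians by animal were -0.751, 0.379 and -0.261 in LD and 0.65, -0.118 and 0.413 in VHD. No gene of the 7 lists that passed did so over all genes or adjusted over the list alone. Of the immune, inflammatory and endothelial lists none passed for VHD against LD post-induction. At baseline the T and NK cell, macrophage, neutrophil and inflammatory lists stood higher in VHD, so the difference draws on the baseline libraries.

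Of the lists that passed in the difference, that of T and NK cells held without any single library. The inflammatory list missed the threshold without LD post-induction 1 (adjusted p = 0.0883) or VHD baseline 1 (0.149), and the macrophage list without LD baseline 2 (0.127), LD post-induction 1 (0.149), VHD baseline 3 (0.0581) or VHD post-induction 3 (0.124). The neutrophil list did so without LD post-induction 3 (0.146), VHD baseline 2 (0.0538), VHD baseline 3 (0.118) or VHD post-induction 2 (0.15), and the ribosomal list without LD post-induction 3 (0.357), VHD baseline 2 (0.33) or VHD post-induction 2 (0.383). The endothelial list did so without LD baseline 2, LD post-induction 1, VHD baseline 1 or 3 or VHD post-induction 3 (0.0763 to 0.721), and oxidative phosphorylation without LD baseline 1 or 2, LD post-induction 2 or 3, VHD baseline 2 or 3 or VHD post-induction 1 or 2 (0.088 to 0.94). The neutrophil, ribosomal and oxidative phosphorylation lists also missed it with a term for the 5 and 7 samples (0.0896, 0.508 and 0.724), with surrogate variables (0.135, 0.71 and 0.743, the last 2 turned) and without VHD baseline 3 and VHD post-induction 2 (0.344, 0.344 and 0.881). Without animal VHD3 the macrophage list (0.355) and the endothelial list (0.571) did. Ribosomal protein medians by animal were 0.65, -0.80 and -0.96 in LD and -0.53, 1.22 and -0.55 in VHD, with the highest value in VHD animal 2. Its libraries cross the division into 5 and 7 samples the other way from those of the other animals that cross it. Both libraries of LD animal 1 lie with the 7. For single genes edgeR called 0 (239 at an unadjusted p under 0.05, fewer than the 919 by chance), limma voom and both limma-trend fits 0, and DESeq2 1.

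At baseline, the comparison of VHD with LD asks which genes differed in liver before the induction. A single gene did: ENSMMUG00000018314, which has no symbol (chromosome 14, 11103782 to 11114307, plus strand, Mmul_8.0.1), stood at 216 ± 52.2 CPM in LD and 1.42 ± 1.93 CPM in VHD (SD, n = 3; log2 fold change -7.22 ± 0.93, adjusted p = 0.0463). It falls outside the naming rule and was chosen after its values were seen. The same animals kept the difference post-induction (166 ± 12.4 against 1.17 ± 0.884 CPM, -7.10 ± 0.93, adjusted p = 0.056), and every LD library stood above every VHD library. Over 21 alternatives at baseline its log2 fold change ran from -9.20 to -6.72 and its adjusted p from 3.03e-19 to 1, and the call held in 9. Without LD baseline 1, 2 or 3 the adjusted p was 0.145, 0.146 or 0.188, and without VHD baseline 1 or 3 it was 0.0861 or 0.371. DESeq2 also called 1 gene. By edgeR 341 genes had an unadjusted p under 0.05, fewer than the 919 that would be met by chance.

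**Figure D4:**
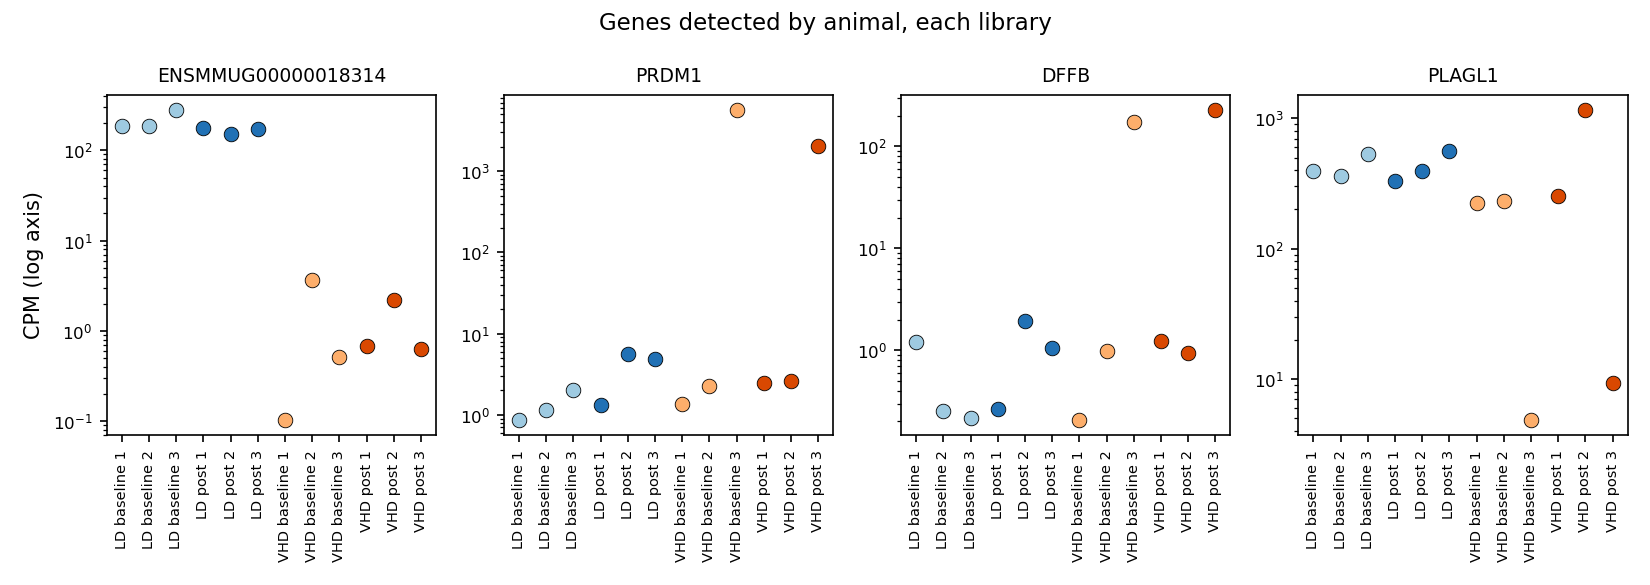
CPM (log axis) of 4 genes in each of the 12 libraries, coloured by group. ENSMMUG00000018314 lies at 152 CPM or above in 6 LD libraries and at 3.63 CPM or below in 6 VHD libraries, and PRDM1, DFFB and PLAGL1 part both libraries of VHD animal 3 from the other 10.

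Some immune lists stood higher in VHD than in LD at baseline, while the interferon, antigen presentation and B and plasma cell lists did not pass. Median deviations of the last by library were 0.502, -0.22 and 0.316 in LD and -0.939, 0.609 and 0.0265 in VHD. Those that stood higher were inflammatory cytokines and NF-kappaB targets (median 0.48, 13 of 15 positive, adjusted p = 0.00235), macrophages and Kupffer cells (0.52, 10 of 10, 0.00235), neutrophils (0.59, 11 of 11, 0.00323) and T and NK cells (0.69, 9 of 9, 0.00346). In the order given, the adjusted p were 0.48, 0.75, 0.73 and 0.48 with an estimated correlation. Coagulation and complement stood lower (-0.12, 24 of 27 negative, 0.0229; adjusted p = 0.886 with an estimated correlation). Values were 1.24 ± 0.45 for RELB, a subunit of NF-kappaB, 0.75 ± 0.31 for the scavenger receptor CD163, 1.57 ± 0.54 for S100A8, 1.25 ± 0.53 for NKG7 and -0.31 ± 0.32 for the clotting factor F9, each with adjusted p = 1, and no gene of the lists passed over all genes or adjusted over the list alone. The inflammatory list missed the threshold without VHD baseline 1 (adjusted p = 0.269), macrophages without LD baseline 2 (0.25), neutrophils without VHD baseline 2 (0.104), T and NK cells without LD baseline 2 (0.139) or VHD baseline 2 (0.146), and coagulation without LD baseline 2 (0.137), VHD baseline 2 (0.394) or VHD baseline 3 (0.953). With a term for the 5 and 7 samples, of which VHD baseline 2 is the only baseline library, the T and NK cell (0.0535), neutrophil (0.139) and coagulation (0.475) lists missed it. Coagulation also did with surrogate variables (0.352, with the direction turned), without VHD baseline 3 and VHD post-induction 2 (0.94) and without animal VHD3 (0.975). By library, of the lists past the threshold only the inflammatory list parted all VHD from all LD libraries. VHD baseline 1 stood below LD baseline 1 in macrophages, below LD baseline 1 and 3 in T and NK cells and below LD baseline 3 in neutrophils. It stood above all LD baseline libraries in coagulation. These lists use the same baseline libraries as the difference of the responses, so their results there are not independent. Leading values of single genes that failed the adjustment (adjusted p = 1) were 3.69 ± 1.11 for DYNAP, 1.77 ± 0.55 for the formin FMNL2, -3.80 ± 1.03 for LYG2 and -1.41 ± 0.41 for the lipid kinase PIK3C2G. The panel had 0.25 ± 0.39 for CYP2E1, -0.41 ± 0.44 for ADH4, 1.14 ± 0.69 for FGF21 and 1.07 ± 0.88 for CYP7A1.

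After the induction the VHD livers stood above the LD livers in cholesterol synthesis and uptake (median 0.45, 14 of 16 positive, adjusted p = 0.000394), cytosolic ribosomal proteins (0.27, 31 of 39 positive, 0.000903) and fatty acid and triglyceride synthesis (0.34, 14 of 21 positive, 0.0258), and below them in heat shock proteins (-0.37, 12 of 12 negative, 0.0258). With an estimated correlation the adjusted p of all 4 was 0.889. Values were 0.61 ± 0.28 for SREBF2, the transcription factor of the cholesterol pathway, 0.64 ± 0.38 for RPS14, 1.89 ± 0.76 for the lipid droplet protein CIDEC and -0.94 ± 0.42 for the co-chaperone BAG3. No gene of these lists passed over all genes or adjusted over the list alone. The cholesterol list missed the threshold without LD post-induction 3 (adjusted p = 0.19) or VHD post-induction 3 (0.241), and the ribosomal list without LD post-induction 2 (0.159) or 3 (0.868) or VHD post-induction 2 (0.922). The fatty acid list did so without LD post-induction 3 (0.575) or VHD post-induction 1 (0.0636) or 3 (0.542), and heat shock without LD post-induction 1 or 3 or any VHD post-induction library (0.0525 to 0.695). Heat shock also did with a term for the 5 and 7 samples (0.061), and the fatty acid, heat shock and ribosomal lists did with surrogate variables (0.241, 0.285 and 0.285). Without VHD baseline 3 and VHD post-induction 2 heat shock (0.18) and the ribosomal list (0.941) missed it, and without animal VHD3 the cholesterol (0.239), fatty acid (0.583) and heat shock (0.0699) lists did. In LD post-induction 1 the cholesterol list stood above every VHD post-induction library (median deviation 0.85 against 0.20, 0.35 and 0.74). That library also stood above VHD post-induction 1 and 2 in fatty acid synthesis and above 1 and 3 in ribosomal proteins, and LD post-induction 2 stood below VHD post-induction 1 and 3 in heat shock. Single genes with the smallest p (adjusted p = 0.999) were Y_RNA (1.42 ± 0.30), LRRC20 (1.22 ± 0.34), PAEP (2.24 ± 0.63) and CD83 (-1.63 ± 0.44). ILRUN (3.37 ± 0.92) rested on VHD post-induction 2, the only library that stood apart in it. By edgeR 0 genes passed (448 at an unadjusted p under 0.05, fewer than the 919 by chance), while DESeq2, limma voom and both limma-trend fits each called 1 lower gene.

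Of mature miRNAs, miR-122, the main miRNA of hepatocytes (miR-122a-5p in the table), held 56.2 to 72.4% of the miRNA counts in 10 libraries. It held 34.9% (95% Wilson interval 34.7 to 35.1) in VHD baseline 3 and 18.7% (18.5 to 18.8) in VHD post-induction 2. The intervals cover counting error only. These 2 libraries had 9.39 and 11.9 miRNA counts per 1000 transcript counts, against 16.6 to 43.5 in the others. Without miR-122 they had 6.12 and 9.67, inside the range of 5.52 to 16.1 of the others. They belong to different animals and time points.

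**Figure D5:**
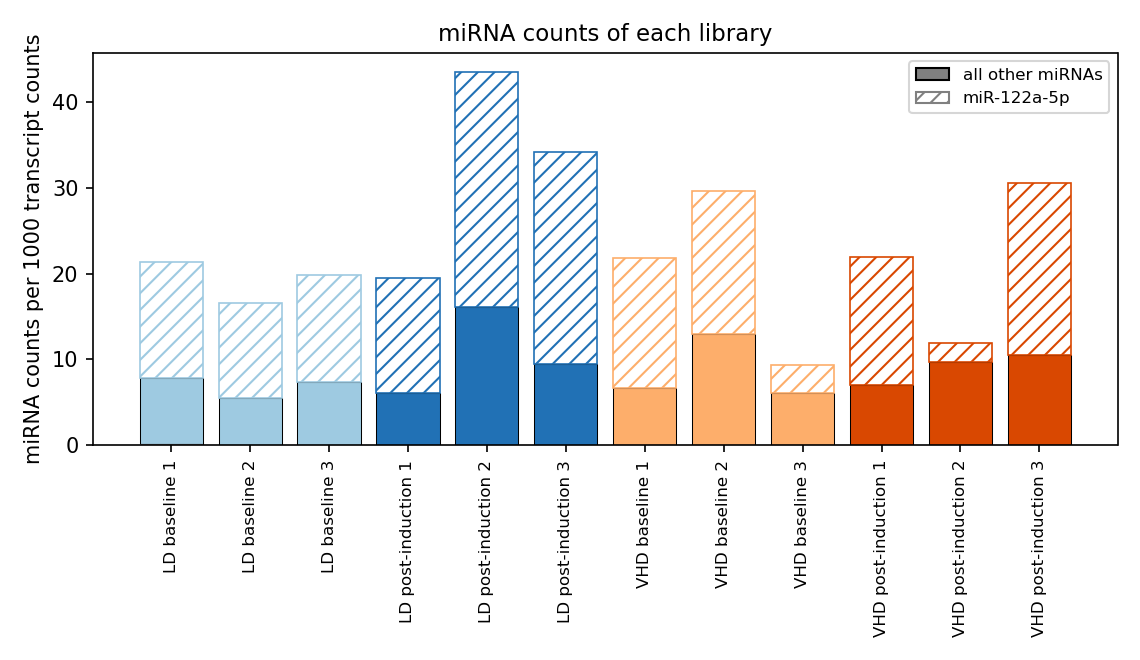
Mature miRNA counts per 1000 transcript counts in each library, as stacked bars of miR-122a-5p (hatched) and all other miRNAs (filled), coloured by group. VHD baseline 3 and VHD post-induction 2 reach 9.39 and 11.9, the other 10 libraries 16.6 to 43.5.

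No single miRNA passed in any of the 6 comparisons. After the induction, over both classes, miR-21-3p was lower in 5 of 6 animals (-2.37 ± 0.67, adjusted p = 0.492), going from 113 ± 59.0 to 13.6 ± 11.8 CPM in LD and from 66.3 ± 28.6 to 18.2 ± 19.4 CPM in VHD (SD, n = 3). The smooth muscle and stromal miR-143-5p was lower in 6 of 6 (-1.69 ± 0.52, adjusted p = 0.492). The major arm miR-21-5p had a value of 0.09 ± 0.79, miR-122a-5p one of -0.06 ± 0.65, the myeloid miR-223 one of 0.12 ± 0.64 and the p53-induced miR-34a-5p one of 0.82 ± 0.57, each with adjusted p = 0.98. By edgeR 2 miRNAs had an unadjusted p under 0.05 for VHD against LD at baseline, 9 in the LD response, 2 in the VHD response, 10 for VHD against LD post-induction, 3 in the difference and 11 in the mean response, where 21 would be met by chance. DESeq2 and limma voom called 0 miRNAs in each.

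Of the miRNA lists the let-7 family, which represses growth genes, stood lower in VHD than in LD at baseline (median -0.29, 10 of 12 negative, adjusted p = 0.0306; 0.474 with an estimated correlation). Post-induction 3 lists stood lower in VHD: the leukocyte miRNAs (-0.12, 7 of 9 negative), the alcohol-linked miRNAs (-0.31, 13 of 16 negative) and the let-7 family (-0.33, 9 of 12 negative), each with adjusted p = 0.0413. With an estimated correlation these adjusted p were 0.382, 0.382 and 0.49. Values were -0.83 ± 0.72 for let-7i-5p at baseline and, post-induction, -0.97 ± 0.90 for miR-342-3p, 1.57 ± 0.91 for miR-182 and -0.60 ± 0.82 for let-7c-5p, and no miRNA of these lists passed adjusted over the list alone. At baseline the let-7 list missed the threshold without LD baseline 1 (adjusted p = 0.14), LD baseline 2 (0.082) or LD baseline 3 (0.0502), and its direction turned without VHD baseline 3 (0.976), 1 of the 2 libraries with the fewest miRNA counts per transcript count. Post-induction the leukocyte list missed it without LD post-induction 1 or 2 or VHD post-induction 2 (0.0573 to 0.974), the alcohol-linked list without LD post-induction 1 or 2 or any VHD post-induction library (0.0535 to 0.29) and the let-7 list without LD post-induction 1 or 2 or VHD post-induction 1 or 2 (0.059 to 0.762). With surrogate variables the let-7 list at baseline (0.436) and all 3 lists post-induction (0.873 each) missed it. Without VHD baseline 3 and VHD post-induction 2 the post-induction lists did as well (0.925, 0.235 and 0.738), and the alcohol-linked list did without animal VHD3 (0.0909). Left unmatched to miR-122a, as the lists were first run, the post-induction lists gave 0 results (adjusted p 0.0525, 0.0926 and 0.0615).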

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

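Chosen after the result was seen were the tests on markers of other cell types, on handling, on differences between animals, on a mislabelled sample and on the share of hepatocytes, and the fit with a term for the 5 and 7 samples.

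The fall of immediate early and other genes after the induction (46 genes, median log2 change -1.84) was set against 3 technical explanations. For the immediate early list the division into 5 and 7 samples is argued against as the cause. VHD animal 2, whose libraries cross the division the other way, had a median of -0.845, and LD animal 1, whose libraries lie on 1 side, had -1.07. With a term for the division the 46 genes had a median of -1.79. They were picked by their fall in these same libraries, so that value is no independent support. A general loss of cells other than hepatocytes is argued against by the 58 markers of 6 other cell types, whose median was -0.0245 (quartiles -0.306 and 0.238). This pooled median could not show a loss of 1 cell type or in 1 class. Macrophage medians, for example, were 0.311, 0.249 and 0.272 in LD and -0.0524, -0.568 and -0.871 in VHD. Handling that differed between the time points stays open, because it cannot be told apart from time: the heat shock list had a median of 0.0371, with animals on both sides of 0, but immediate early genes may respond to handling when heat shock genes do not. The heat shock list also lacked HSPA1A, HSPA1B, HSP90AA1 and HSPB1, which matched no identifier. The effect of ethanol, age and repeated biopsy remain open too, untested, since no animal went without ethanol.

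The gene without a symbol that stood low in every VHD library (ENSMMUG00000018314) could reflect an inherited difference between animals that follows drinking class by chance. In that case other such genes should divide the animals 3 to 3 in other ways, and over the 9 other divisions 0 did, so this remains open with so few animals. A mislabelled sample was asked of the 26 genes that were on in both libraries of some animals and off in both of the others: the highest of the 35 other pairings of libraries also gave 26, because most of these genes mark VHD animal 3 alone, so a swap among the other animals cannot be told apart. The limits that define these genes, and the criterion for reading them, were set after a first, stricter form had left 6 genes. Reads from a related gene copy were not tested, and drinking class itself stays among the open explanations.

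Explanations were sought for the low miRNA counts of VHD baseline 3 and VHD post-induction 2, relative to their transcript counts. Across 134 small nucleolar RNA genes of the C/D class, which are not independent replicates, the median log2 ratio to the other 10 libraries was -0.972. Shorter genes were lower in these libraries (Spearman rho 0.366 with length, 0.413 and 0.31 in each). A loss of short inserts would give this, but it should also lower the miRNAs other than miR-122. Without miR-122 the 2 libraries had 6.12 and 9.67 miRNA counts per 1000 transcript counts, inside the range of 5.52 to 16.1 of the other 10. A loss of mainly 1 abundant miRNA would give this, but the range is wide and the sum can hide falls of other miRNAs. The let-7 family had median log2 deviations of -1.8 and -1.47 in these libraries, and 0.00907 or more in the others. Leukocyte miRNAs had -0.69 and -2.29, while the miR-17-92 list had -0.00172 and 0.389. So miR-122 was not the only miRNA that stood low, and how far a loss of short inserts accounts for the low counts cannot be told. A large loss of hepatocytes is argued against by the 8 hepatocyte markers, whose median log2 ratio to the other libraries was -0.113 (-0.247 and 0.0204 in each). Other lists were mixed: pericentral hepatocyte markers had -0.842 and -0.313, the cytochrome P450 list -0.378 and -0.426, and periportal markers -0.203 and 0.354. Markers of adipocytes and mesothelium had 0.699 and 0.849. A smaller loss of hepatocytes therefore stays open. A loss of short inserts and a loss of mainly miR-122 do not exclude each other. Beyond the share of hepatocytes no biological explanation was tested, and the 2 libraries share the class but neither animal nor time point.

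The following gene lists differed between the classes in the test of the difference of the responses, and none did with an estimated correlation (adjusted p 0.419 to 0.823). The immune, inflammatory and endothelial lists among them did not pass for VHD against LD post-induction. The macrophage and Kupffer cell list (adjusted p = 0.00307) had median log2 changes of 0.311, 0.249 and 0.272 in the LD animals and -0.0524, -0.568 and -0.871 in the VHD animals. The T and NK cell list (0.000491) had 0.545, 0.497 and 0.254 in LD and 0.339, -0.621 and -0.6 in VHD. For neutrophils (0.0162) the medians were 0.257, 0.956 and 0.71 in LD and 0.535, -1.31 and 0.128 in VHD. The liver sinusoidal endothelial list (0.0288) had 0.873, -0.0138 and -0.152 in LD and -0.107, -0.0735 and -0.974 in VHD. Inflammatory cytokines and NF-kappaB targets (0.00291) had -0.108, -0.146 and 0.0873 in LD and -0.683, -1.26 and -0.167 in VHD. For cytosolic ribosomal proteins (0.000156) the medians were 0.648, -0.803 and -0.958 in LD and -0.53, 1.22 and -0.547 in VHD. Oxidative phosphorylation (0.0288) had 0.534, -0.425 and -0.522 in LD and -0.172, 0.68 and -0.233 in VHD.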

How the results depend on the processing

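Chosen after seeing the data were the fits without VHD baseline 3 and VHD post-induction 2, without animal VHD3, with a term for the 5 and 7 samples, with 2 surrogate variables, without small RNA genes, without miR-122 and with miR-122a unmatched. In every gene-level setting the 49 genes of the mean response kept their direction, with the median log2 change of those that fell between -2.02 and -1.61. These genes were picked in the same libraries, so their kept direction is no independent support. A term for the animal cut the mean response to 4 genes and ended the call of its p53 list. With it alone 3 lists passed: macrophages, lower in the VHD response (adjusted p = 0.0433), B and plasma cells, higher in the difference (0.0449), and cytochrome P450, lower in the mean response (0.0441). The rise of the B and plasma cell list goes against the fall of the other immune lists in the difference. Between LD and VHD, where the term was the number in the titles, heat shock at baseline passed with it alone, as lower in VHD (adjusted p = 0.0442). These terms changed no other gene count and no other list call. Where no cause is named below, the cause was not tested.

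The gene of the baseline comparison was lost (count 0) with upper-quartile factors, with the 1 CPM filter, in the fit to the compared groups alone, on transcripts, without animal VHD3, without the 2 libraries, with the split term and with surrogate variables, and leaving out 1 library gave 0 to 1. Counts of the LD response were 53 by DESeq2 and 3 with surrogate variables. Those of the VHD response were 64 by DESeq2, 3 with the split term, 48 with surrogate variables, 1 without the 2 libraries and 0 to 1 leaving out 1 library. Post-induction 1 gene passed by DESeq2, without a filter, by voom, in the fit to the compared groups alone and by both limma-trend fits, and in the difference 1 by DESeq2. The mean response gave 269 genes by DESeq2, 4 with a term for the animal, 103 with the split term (37 shared), 372 with surrogate variables (43 shared), 32 without the 2 libraries (27 shared), 0 without animal VHD3, 0 on transcripts and 0 to 71 leaving out 1 library. The mean response of miRNAs gave 4 with surrogate variables.

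With an estimated correlation and with fry 0 gene lists and 0 miRNA lists passed in each comparison that had any. Leaving out 1 library gave 2 to 11 gene lists at baseline, 6 to 13 in the LD response, 0 to 8 post-induction and 4 to 12 in the mean response, and post-induction 2 passed without the 2 libraries, without animal VHD3 and with surrogate variables. With the split term 4 gene lists passed at baseline (2 shared), 9 in the LD response (6 higher, 3 shared, 1 of these turned), 7 in the VHD response (5 shared), 5 in the difference (4 shared) and 7 in the mean response (5 shared). With surrogate variables these were 7 (4 shared), 8 (5 higher, 3 shared, 1 of these turned), 7 (5 shared), 5 (4 shared) and 7 (5 shared). Counts of miRNA lists leaving out 1 library were 0 to 2 at baseline, 0 to 1 in the VHD response, 0 to 4 post-induction and 0 to 1 in the difference and the mean response. At baseline 0 miRNA lists passed without the 2 libraries, without animal VHD3 and with surrogate variables, and post-induction 0 without the 2 libraries, with surrogate variables and with miR-122a unmatched. The VHD response gave 1 without animal VHD3, 1 with the split term and 2 with surrogate variables, the difference 1 without animal VHD3, and the mean response 1 with the split term and 1 with surrogate variables.

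Directions turned for ribosomal proteins in the LD response with the split term (adjusted p = 5.72e-06) and with surrogate variables (0.000134). With surrogate variables they also turned for coagulation at baseline (0.352), in the LD response (0.655) and in the mean response (0.854), for oxidative phosphorylation (0.743) and ribosomal proteins (0.71) in the difference, and for let-7 post-induction (0.873). The let-7 list at baseline turned leaving out 1 library (adjusted p from 0.00261 to 0.976, the highest without VHD baseline 3), without the 2 libraries (0.967) and without animal VHD3 (0.983).

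Of the other values under the settings laid down beforehand 6542 kept direction and side of the threshold, 377 lost and 62 gained a call, and 113 changed direction without a call on either side. Under those added later the numbers were 1681, 95, 32 and 67. Of the named values 350 had no call to lose, so this tally does not measure how well calls held. Calls of named genes in the mean response held in 11 (IL1RN) to 23 (KLF6) of 26 alternatives. Depth and spread limit single genes to large changes. In simulated data, which lacked the shared structure of the real libraries, 32.8% of genes changed 4-fold were recovered in the VHD response and 89.6% in the mean response.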

Other observations

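The genes of the next 2 paragraphs and the limits that define them were chosen after the values were seen, and the counts over other splits were planned.

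In animal VHD3 a set of genes stood apart from the other 5 animals at both time points, 18 genes on in its 2 libraries alone and 7 off in them alone. PRDM1, a repressor that drives plasma cell formation, stood at 5601 CPM in VHD baseline 3 and 2070 CPM in VHD post-induction 3, against 5.56 CPM or less in the other 10 libraries. DFFB, the nuclease of apoptotic DNA fragmentation, had 171 and 224 CPM against 1.94 or less. FAM50B, known as an imprinted gene in primates, had 71.5 and 99.1 CPM against 5.25 or less. In the other direction PLAGL1, also known as imprinted, had 4.85 and 9.34 CPM against 225 to 1149, and the kinase CDK17 had 11.7 and 14.4 CPM against 167 to 776. The counts of PLAGL1 and CDK17 looked close to proportional over the libraries, and whether they share reads was not examined.

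A further 9 genes were off in VHD baseline 3 and VHD post-induction 2 alone, 6 of them small nucleolar RNAs. SNORD29 had 87.9 and 59.4 CPM there, against 3708 to 15980 in the other 10. In VHD post-induction 3 alone 7 genes were on, among them DOCK8, RUNX2 and LPAR1, and in VHD post-induction 2 alone 2, among them ILRUN. Here on means above the gap and not absent elsewhere. Before TMM scaling RUNX2 had 10.9 CPM in VHD baseline 3, from the same animal, and DOCK8 had 10.5 CPM in VHD baseline 2. SLC15A2, a peptide transporter, was on in the 5 samples with positive values on component 1 (54.5 to 186 CPM before TMM scaling) and had 6.58 or less in the other 7.

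Other splits of the libraries were counted for each comparison. With 6 libraries there are 10 splits, too few for a share under 0.05. For genes the real split at baseline gave 1 and the highest other 0 (1 split as large), the LD response 0 and 0, the VHD response 0 and 8, and VHD against LD post-induction 0 and 695 (10 splits as large in each of these 3). The split with 695 sets LD post-induction 2 and 3 and VHD post-induction 3 against the others, which follows the 5 and 7 samples but for VHD post-induction 1 and points to a structure of the samples. For miRNAs the real counts were 0 and the highest others 0, 1, 9 and 1, the 9 in a split of VHD libraries along the 5 and 7 samples. For gene lists the real counts were 5, 6, 7 and 4 and the highest others 20, 18, 15 and 16, with 5, 8, 4 and 10 splits as large. For miRNA lists the real counts were 1, 0, 0 and 3 and the highest others 3, 1, 4 and 2, with 6, 10, 10 and 1 splits as large.

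With all 12 libraries 100 of 200 splits were drawn. The 49 genes of the mean response were matched or passed by 5 of the 100 splits, the real one included, so chance could not be excluded, and the highest other gave 1243 genes, which points to a structure of the samples. Like the real split it parts all 6 pairs of libraries of 1 animal, but it sets LD baseline 2 and 3, LD post-induction 1, VHD baseline 1 and 3 and VHD post-induction 2 against the rest; it is the only 1 as large among the 16 other splits that part 6 pairs. It keeps the 5 samples on 1 side, and with a term for them the real split gave 103 genes. The difference of the responses gave 0 genes (highest other 1590, which again points to a structure of the samples), so all 100 were as large. Of miRNAs the difference and the mean gave 0 (highest others 44 and 70), and of miRNA lists 0 (4 and 4), and all 100 were as large. For gene lists 46 of 100 splits reached the 7 of the difference (highest other 19) and 27 the 10 of the mean response (highest other 21), so chance could not be excluded for either.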
